A study of Homo sapiens with 13 samples.

How the data were processed

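Circular RNA junction reads were measured in 5 short-read and 8 long-read libraries of colorectal cancer lines and of the tissues of 1 donor. Per the labels' protocols, short-read libraries were stranded total RNA libraries depleted of ribosomal RNA and enriched by exome capture, and long-read libraries were made from RNA treated with RNase R, reverse transcribed by rolling circle and debranched before Nanopore or PacBio sequencing. Per the labels, lines and tissues were extracted by different methods, so extraction cannot be told apart from the comparison of lines with tissues. Per the submitters' processing notes, STAR 2.7.3a, featureCounts 1.6.0 and the build hg38 were used; which tool called the short-read circles is not given in the sources used here.

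The authors deposited raw read counts per circle for short reads and, separately, raw read counts per circular transcript for isoCirc and for CIRI-long. The authors also deposited a short-read table named TPM, whose values are RPM: each equals the count times 1 factor per library, with no length term. CPM here is relative to all circle reads of the library. The long-read tables give no strand and share one set of transcripts; the smallest non-zero value was 1 in isoCirc and 2 in CIRI-long, so CIRI-long junctions with a single read were not analysed here. No per-sample column was left unused.

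Transcripts with the same chromosome, start and end were summed into 1 junction. Start positions of the tables were put on 1 base convention, chosen because 945 isoCirc and 34 CIRI-long junctions then coincided with short-read junctions and 0 did under the 8 other offsets. Coordinates are 1-based. Junctions were placed on a GENCODE annotation of the same build to find exon boundaries, introns, untranslated regions and host genes; exon numbers are those of the deposited short-read table. Y-linked genes and XIST were left out (95 short-read and 81 long-read entries). A junction counted as detected at 2 reads and was sought at 1 read in the other table, at exact coordinates.

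Lines and tissues were compared with edgeR 4.0.16 (quasi-likelihood test, TMM, its filter by expression, Benjamini-Hochberg at 0.05) in R 4.3.3, with DESeq2 1.42.0 as an alternative. Gene lists were tested with camera in limma 3.58.1 on log2 CPM of host gene sums (prior count 2, preset correlation 0.01, estimated correlation beside it, at least 3 members). The edgeR fit was tested on simulated counts with 200 changed genes, and ratio intervals on 500 draws (coverage 95.6%). Comparisons of single libraries used exact conditional intervals of the ratio of reads, a count of junctions with at least a 4-fold CPM difference and 10 reads in the higher library, and 10000 random gene lists matched on mean expression, with a floor of 3 reads. Overlaps had exact Clopper-Pearson intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

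Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took at most 1 junction per host gene and left out the mitochondrial genome and junctions with no gene symbol: the 10 junctions of highest mean CPM per set of libraries; the 10 per direction (6 for tissues, with the same direction in CIRI-long) with the interval bound farthest from equality; the 10 most read junctions found by one method alone; the 3 per short-read line with the largest bound against the other 4 lines; and the 4 most read members of each gene list. The lists were well-described circle hosts, smooth muscle, fibroblast and matrix, endothelial, immune, enteric neural and glial, epithelial, differentiated colonocyte and goblet, hepatocyte, Wnt and colorectal driver, cell cycle, mesenchymal transition, and splicing and circle formation genes. The C3, CPS1, SERPINA1, CP and ABCC2 members of the hepatocyte list can also be made by other tissues. Some junctions and list members that the rule would name are not reported here.

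Alternatives were other normalizations, no filter on low counts, the other caller, host gene sums, other read minimums, a tolerance of 3 bases, thinning, and leaving out libraries; more were chosen after values had been seen. Because the filter left 1 junction, library totals were taken over all junctions in every fit, a choice made after the first output. TMM factors of the main fit rest on that junction alone and carry little information; factors from all junctions, added later, and plain library totals also gave 0 calls by edgeR. Size factors from DESeq2 and the DESeq2 test on the filtered junction were not run for the same reason, and strand-matched caller overlap was not run because the long-read tables hold no strand.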

Results

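Circular RNAs form when the end of an exon is spliced back to the start of the same exon or of one upstream, and each is recognised by reads across this back-splice junction. Junction reads were tabulated for 13 libraries of colorectal cancer material. The 5 short-read libraries came from the colorectal cancer lines HCT116, HT29, LoVo, SW480 and SW620, 1 library per line. SW480 was derived from a primary tumour and SW620 from a later metastasis of the same patient. The 8 long-read libraries were made by rolling-circle amplification, which copies a circle many times into a single read. HCT116 was sequenced in 3 of them (a Nanopore pilot, a Nanopore run and a PacBio run), HT29 and LoVo in 1 PacBio library each, and normal colon mucosa, primary colon tumour and liver metastasis of a single donor in 1 PacBio library each. Long reads were called by isoCirc, used as the main caller here, and by CIRI-long.

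Short-read libraries held 16488 to 35588 junction reads (mean 23196 ± 7860, SD, n = 5). The long-read libraries held 755 to 19493 reads by isoCirc and 9750 to 67759 by CIRI-long. Single junctions took large shares of the isoCirc reads, with a mean of 21.7% ± 13.6 (SD, n = 8) for the leading junction against 0.759% ± 0.176 (SD, n = 5) in the short-read libraries. No line or tissue had replicate libraries of one kind, and the 3 tissues shared 1 donor, so p-values describe these libraries. Intervals are exact 95% intervals and cover counting error only, since amplified reads are not independent molecules.

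**Figure D1:**
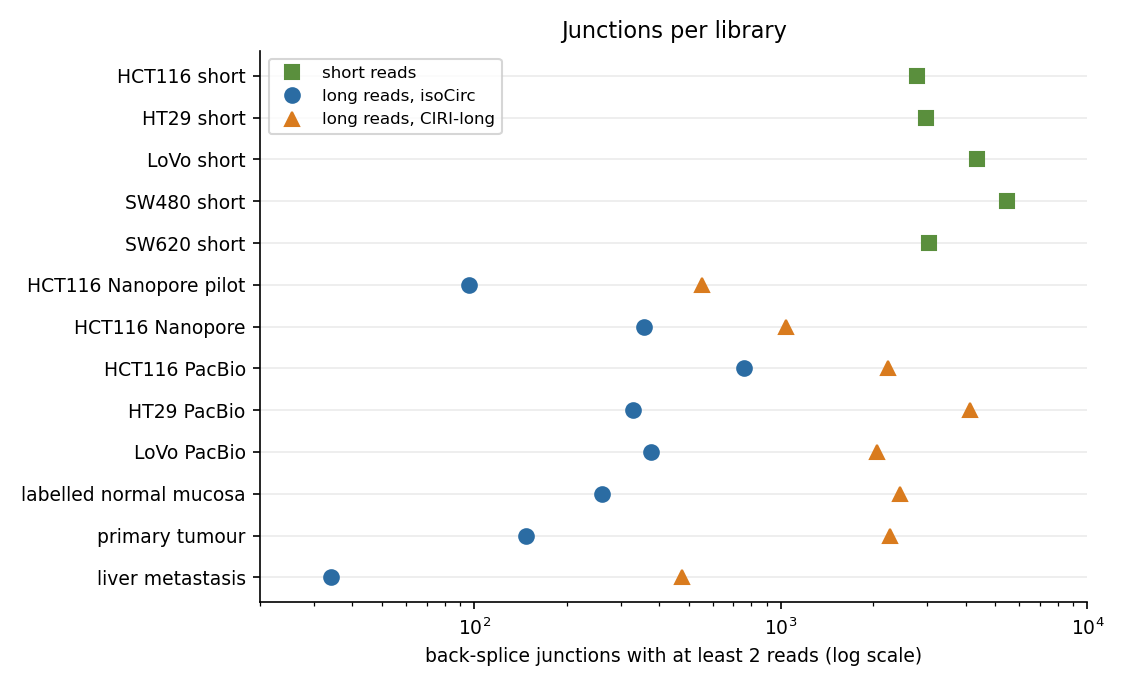
Back-splice junctions with at least 2 reads (x axis, log scale) in each library (y axis), 1 point per library and table. Short-read libraries lie between 2783 and 5449 junctions, isoCirc between 34 and 756, and CIRI-long between 476 and 4124, above isoCirc in all 8 long-read libraries.

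The short-read libraries addressed which circles colorectal cancer lines carry and how far the lines share them. The leading junction was SPECC1 exon 4 (chromosome 17, 20204333 to 20205912, hg38) with 4616 ± 2775 CPM (SD, n = 5). Next came exon 2 of FAT1, an atypical cadherin, with 4123 ± 1710 CPM (chromosome 4, 186706563 to 186709845), and exons 2 to 5 of MAN1A2, a mannosidase of glycoprotein processing, with 3979 ± 1473 CPM (chromosome 1, 117402186 to 117420649). Exon 4 of CDYL (3537 ± 1553 CPM), exon 2 of the kinase gene HIPK3 (3323 ± 1256 CPM), exons 3 to 5 of ZKSCAN1 (2761 ± 1183 CPM), exons 2 to 6 of SETD3 (2295 ± 1017 CPM) and exons 15 to 16 of the chromatin remodeller SMARCA5 (2214 ± 875 CPM) were likewise read in all 5 lines. TNFRSF21 exons 2 to 3 ranged from 688 to 7386 CPM and peaked in HT29 with 138 reads. All of these junctions had both ends at annotated exon boundaries.

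Several circles belonged almost entirely to single lines. Exons 3 to 11 of CYP24A1, whose product inactivates vitamin D, had 169 reads in HCT116 (10250 CPM) and 8 in the other 4 lines together, a ratio of 127 (63.2 to 300.1; chromosome 20, 54157169 to 54171670). HCT116 also held 17 reads of USP34 exons 21 to 48, at least 34.2-fold above the other lines, where it had 0 reads (floor of 3 reads over the 4 lines), and 6 of PTOV1. In HT29, ADAMTS6 exons 2 to 7 had 80 reads against 5 in the other lines (ratio 83.3, 34.3 to 264), and PTK2 exons 3 to 10, from the focal adhesion kinase gene, had 44 against 8 (ratio 28.6, 13.3 to 70.4). GNAQ exons 2 to 3 had 6 against 0. In LoVo, exons 6 to 12 of the semaphorin gene SEMA3C had 72 reads against 13 (ratio 18.9, 10.4 to 37.1), COCH exons 3 to 7 had 22 against 3 (ratio 25.0, 7.51 to 130) and CTBP2 exon 3 had 11 against 0. SW480 held CERS6 (44 reads), SFMBT1 (16 reads) and AHNAK (13 reads) at 0 in the other lines. SW620 held GLI3 (18 reads) and SDK1 (15 reads) at 0 and PROX1 with 39 reads against 2 (ratio 100.1, 25.9 to 856).

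Each line had 3722 ± 1150 junctions with at least 2 reads (SD, n = 5). Of 10839 such junctions, 558 (5.15%) were found in all 5 lines and 6906 (63.7%) in 1 line. Across the 2033 junctions compared, read counts of the 10 pairs of lines had a mean Spearman rho of 0.277 ± 0.025, where junctions are not independent replicates. SW480 and SW620, from the same patient, had a rho of 0.259, rank 8 of 10. The number of junctions depended on the read minimum, with means of 10562 at 1 read and 835 at 5 reads.

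Among the 13 gene lists fixed before the data were examined, the 30 well-described circle hosts took 5.70% ± 1.14 of short junction reads (SD, n = 5), led by MAN1A2 (842 reads), UBAP2 (571 reads), FAT1 (531 reads) and PTK2 (493 reads). Cell cycle genes took 0.349% ± 0.107, led by ATAD2 (78 reads) and the DNA polymerase gene POLA1 (43 reads). Epithelial genes took 0.213% ± 0.092, led by MYO5B (65 reads), GRHL2 (48 reads), SHROOM3 (46 reads) and ESRP1 (39 reads). Wnt and colorectal driver genes took 0.212% ± 0.035, led by SMAD2 (81 reads) and BRAF (61 reads). Differentiated colonocyte and goblet genes took 0.0958% ± 0.0373. Splicing and circle formation genes took 0.0665% ± 0.0193, mesenchymal transition genes 0.0426% ± 0.0208, smooth muscle genes 0.0410% ± 0.0207 and enteric neural and glial genes 0.0369% ± 0.0224. Fibroblast and matrix genes (0.0169% ± 0.0184), hepatocyte genes (0.0136% ± 0.0095), endothelial genes (0.01003% ± 0.0165) and immune genes (0.00510% ± 0.00585) were near 0.

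The pair SW480 and SW620 asked how circles differ between a primary tumour line and a metastatic line of the same patient. SW620 held 39 reads of PROX1 exons 2 to 4 (chromosome 1, 213996469 to 214011715), from a homeobox gene of lymphatic and gut development, against 0 in SW480, at least 24.5-fold higher (floor of 3 reads per library). PDE4D exons 7 to 11 (21 reads, at least 13.2-fold), GLI3 exons 5 to 10, from a Hedgehog pathway transcription factor gene (18 reads, at least 11.3-fold), MAST2 and SDK1 (15 reads and at least 9.41-fold each), PHLDB2 (14 reads, at least 8.79-fold) and ZDBF2 (12 reads, at least 7.53-fold) also had 0 reads in SW480. RHOBTB3 exons 6 to 7 rose from 3 to 39 reads (ratio 24.5, 7.78 to 124), ZBTB46 exons 2 to 3 from 21 to 130 (ratio 11.7, 7.31 to 19.5) and PRKD3 exon 2 from 4 to 30 (ratio 14.1, 4.98 to 55.2). Among the 25 measured well-described circle hosts, summed reads of RHOBTB3 (5 and 49 reads, ratio 18.5), CORO1C (20 and 39 reads, ratio 3.67), FAT1 (97 and 142 reads, ratio 2.76) and 6 others were higher in SW620 by their intervals on library totals.

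SW480 held more reads of DNA2 exons 2 to 3, from a nuclease and helicase gene of DNA replication (85 and 1 reads, ratio 45.1, 7.89 to 1804; chromosome 10, 68468123 to 68470163). Circles of CERS6, a ceramide synthase gene (44 reads, at least 7.79-fold), CCDC126 (34 reads, at least 6.02-fold), MTUS1 (32 reads, at least 5.67-fold), CCSER1 (29 reads, at least 5.13-fold), the stress kinase gene MAP2K4 (28 reads, at least 4.96-fold) and USP42 (21 reads, at least 3.72-fold) had 0 reads in SW620. CCDC134 (71 and 4 reads, ratio 9.43, 3.52 to 35.6), GSE1 (38 and 1 reads, ratio 20.2, 3.41 to 818) and LZIC (37 and 2 reads, ratio 9.83, 2.53 to 84.2) completed the set. Of 7 measured epithelial genes, the adhesion gene EPCAM (16 and 1 reads, ratio 8.50), the epithelial splicing regulator gene ESRP1 (19 and 1 reads, ratio 10.1), MYO5B (35 and 2 reads, ratio 9.30) and the transcription factor gene GRHL2 (13 and 0 reads) were higher in SW480 under all 3 scalings, with intervals above 1. SHROOM3 was higher in SW620 (11 and 14 reads) by its interval on library totals alone. SMARCA5, MBOAT2, MAN1A2 and HIPK2 were the circle hosts higher in SW480 on library totals.

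With 1 library per line, these counts compare libraries and have no replicate check. By library totals, 67 junctions with at least 10 reads in the higher library differed at least 4-fold, 31 higher in SW480 and 36 higher in SW620 (46.3% higher in SW480). TMM factors shifted log2 ratios by 0.47 toward SW480 and gave 77 and 32 (70.6%), and the deposited RPM scale, whose total is not given in the sources used here, shifted them by 1.10 and gave 240 and 14 (94.5%). With library totals, a minimum of 5 reads gave 31 and 72 and of 20 reads 31 and 9. The balance of directions thus moved with the scaling and the minimum. With the floor of 3 reads, a junction needed more reads to reach 4-fold in SW480 (35588 reads in total) than in SW620 (18903). The SW480 count on library totals therefore stayed at 31 at each minimum. The split by direction depends on depth and does not compare the lines alone. Of the 25 circle hosts, 4 were higher in SW480 and 9 in SW620 by their intervals on library totals, and 10 and 6 with TMM factors. On the deposited scale 13 were higher in SW480 and only RHOBTB3 in SW620. With the floor of 3 reads, the median log2 ratio of SW480 over SW620 was −0.176 for the epithelial list (9 members, 4 above 0 and 5 below 0). The floor put PLS1 (5 and 2 reads) and CDH1 (4 and 1 reads) below 0. Without it their ratios were 1.33 and 2.12, with intervals that included 1. The count below 0 is therefore not a count of genes lower in SW480. The epithelial median lay at percentile 86.8 of 10000 random lists matched on expression, whose median was −0.591. The median of all hosts was −0.913. A host at or under the floor in both libraries takes this value from the library totals alone, so it shows no shift toward SW620. The median of the circle hosts was −0.303, at percentile 12.2 of their matched random lists, whose median was 0.0442.

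**Figure D2:**
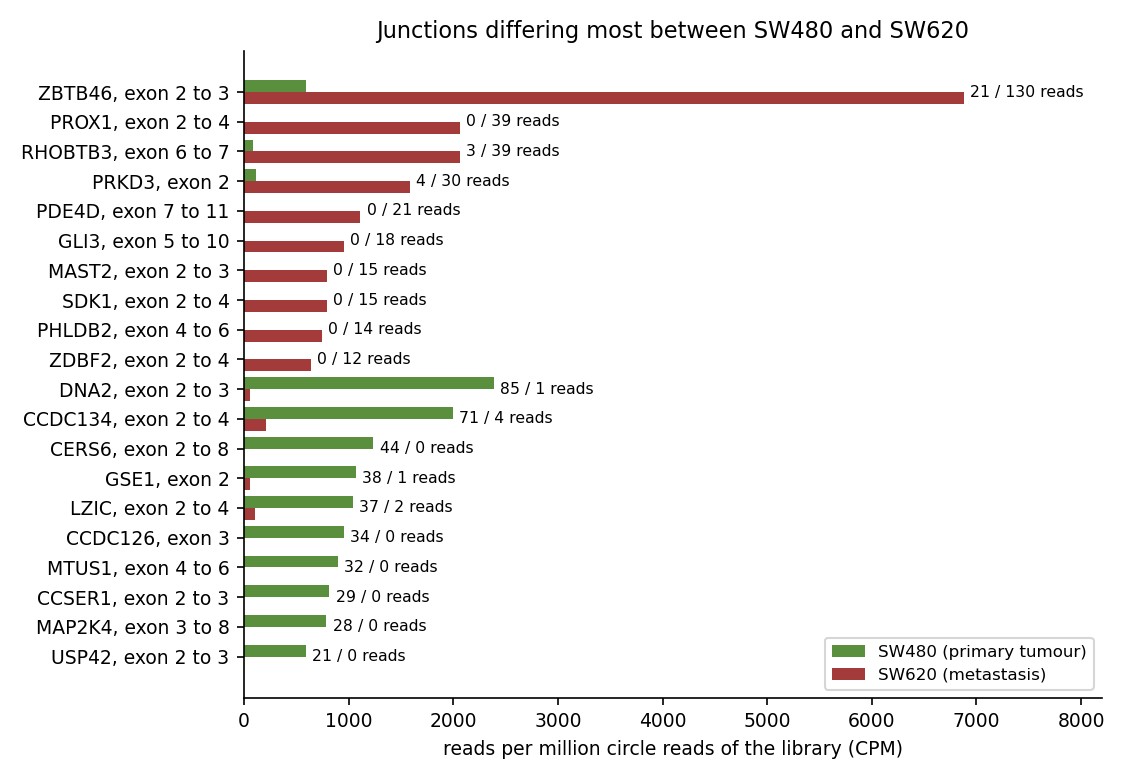
CPM (x axis) of the 20 junctions that differed most between SW480 and SW620 (y axis, host gene and exons as numbered in the deposited table), 1 bar per library with raw reads of SW480 and SW620 beside it. ZBTB46 stands highest with 6877 CPM in SW620, and 13 of the junctions had 0 reads in 1 of the libraries.

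Short and long reads of the same line were compared to learn how far the methods find the same circles. In the 3 PacBio lines isoCirc recovered HIPK3 exon 2 in HT29 alone (22 reads), SPECC1 exon 4 in HCT116 alone (7 reads) and TNFRSF21 exons 2 to 3 in HT29 (4 reads) and LoVo (7 reads). Other abundant short-read circles had no long read by either caller in any library: MAN1A2 exons 2 to 5 (210 short reads over the 3 lines), CYP24A1 (177 reads), ARHGAP5 exon 2 (138 reads), FBXW7 exons 2 to 3 from a ubiquitin ligase gene (131 reads), ZBTB44 exon 2 (112 reads), ASPH (100 reads), ESYT2 (98 reads), FGD6 (97 reads), PTK2 exons 3 to 5 (91 reads) and SEMA3C (84 reads). In the other direction, 82 junctions with isoCirc reads in the 3 lines and CIRI-long reads in any long-read library had no read in the 5 short-read libraries. By isoCirc reads they were led by exon 6 of the histone methyltransferase gene ASH1L with 3944 isoCirc reads (chromosome 1, 155415744 to 155415923; its 32 CIRI-long reads were in the HCT116 Nanopore library), PTGR2 with 1190 (chromosome 14, 73879096 to 73880176), a junction in the untranslated region of TNS4 with 926 (chromosome 17, 40476286 to 40476439), PDIA4 with 373, SRRM2 with 211, OGFOD1 with 168, ZNFX1 with 116, LAPTM4A with 114, CDV3 with 107 and DCUN1D4 with 97. In the 3 PacBio lines the highest mean CPM after ASH1L among junctions of named genes belonged to the small GTPase gene RAC1 exons 2 to 3 (934 of its 939 reads in HT29), RFX2 exons 5 to 6 (526 reads, HT29), the nuclear pore gene NUP160 exons 5 to 7 (391 reads, LoVo), TNS4, PDIA4, PTGR2, TMBIM1 (41 reads in HT29 and 181 in LoVo), SRRM2 and AFF1 exons 3 to 4 (859 reads, HCT116).

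Of short-read junctions with at least 2 reads, 3.97% ± 1.69 (SD, n = 3) were found by isoCirc in the same line: 5.14% in HCT116 (4.35 to 6.02), 4.75% in HT29 (4.01 to 5.57) and 2.04% in LoVo (1.64 to 2.50). The share rose to 10.0% at 5 short reads and 22.4% at 20 short reads. Within a PacBio library the matched line had the highest recovery in HT29 (4.75%, with 3.88% for HCT116 and 3.14% for LoVo short reads). In the HCT116 and LoVo PacBio libraries HT29 short reads had the highest percentage, 5.45% (4.66 to 6.33) and 2.42% (1.90 to 3.04). These intervals overlapped those of the matched line. By count, both libraries shared most junctions with LoVo short reads. The HCT116 library shared 176 with LoVo, 162 with HT29 and 143 with HCT116, and the LoVo library 89, 72 and 59. Of isoCirc junctions with at least 2 reads, 81.2% ± 5.4 (SD, n = 3) were not found by short reads of the same line, and 65.1% of those with both ends at annotated exon boundaries. Junctions with at most 1 such end could hardly be found, since 99.2% of all short-read junctions had both ends at boundaries. Across 612 junctions, a set fixed after values had been seen, the mean Spearman rho was 0.155 for matched and 0.0522 for mismatched lines (exact permutation over 6 assignments, one-sided p = 0.167, the smallest possible); over junctions read by both libraries of a pair the values were 0.133 and 0.107 (exact permutation, one-sided p = 0.333).

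**Figure D3:**
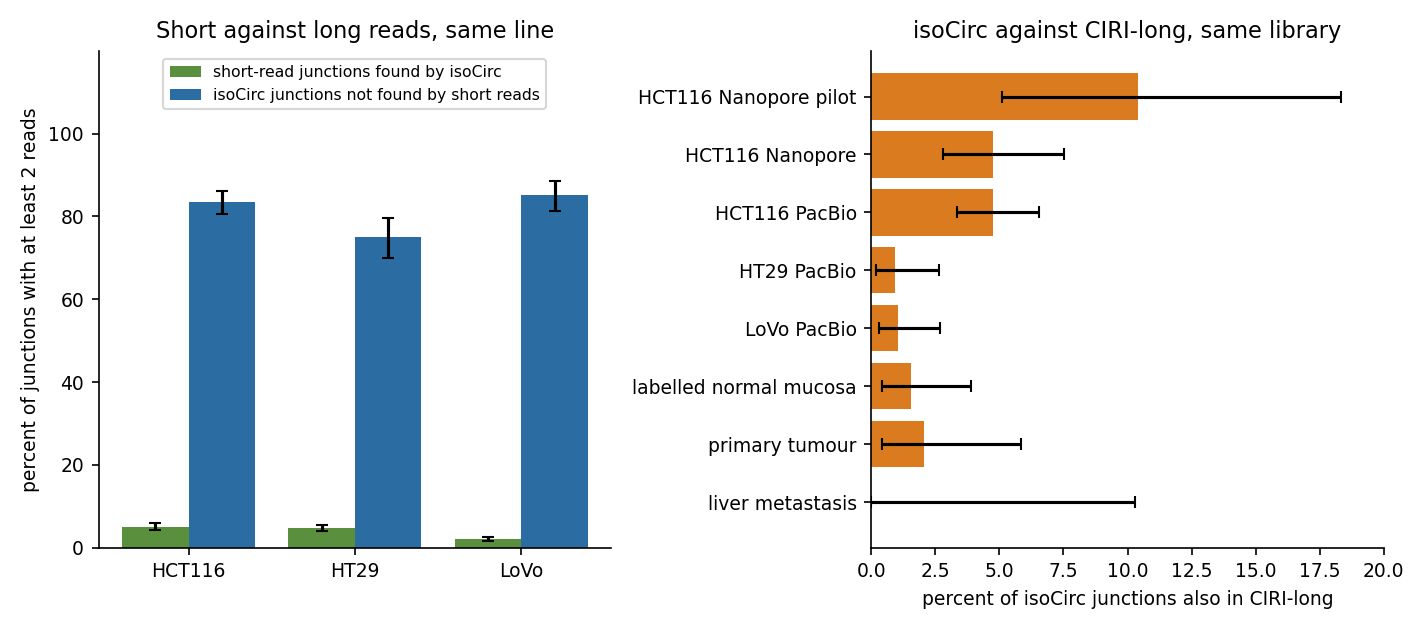
Left, percent (y axis) of short-read junctions found by isoCirc and of isoCirc junctions not found by short reads in HCT116, HT29 and LoVo. Right, percent (x axis) of isoCirc junctions also called by CIRI-long in each long-read library (y axis). Bars are single libraries and error bars exact 95% intervals; recovery stays between 2.04% and 5.14% on the left, and the caller share reaches 10.4% in the Nanopore pilot.

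The callers were compared on the same long-read libraries. isoCirc junctions more often had both ends at annotated exon boundaries, 41.7% ± 13.2 against 1.62% ± 1.09 for CIRI-long and 99.4% ± 0.1 for short reads (SD, n = 8, 8 and 5). The short-read table names its circles by transcript and exon number, so its 99.4% may follow from how circles were listed there. Coding exons held 55.9% ± 15.6 of isoCirc and 40.6% ± 10.3 of CIRI-long junctions, untranslated regions 10.2% ± 3.4 and 19.5% ± 5.8, and introns 20.9% ± 10.2 and 26.3% ± 14.0. The mitochondrial genome gave 33.7% ± 19.8 of CIRI-long reads, up to 69.6% in the Nanopore pilot, and 0 isoCirc reads. Median circle length was 187 ± 18 bases by isoCirc and 108 ± 11 by CIRI-long. CIRI-long called more junctions with at least 2 reads in 8 of 8 libraries (mean log2 ratio of isoCirc to CIRI-long −2.84 ± 0.97; median ratio 7.56; two-sided exact sign-flip permutation p = 0.00781, the smallest possible). With the 3 HCT116 libraries averaged into 1 value, so that each line or tissue counted once, the mean log2 ratio was −3.16 ± 0.83 (n = 6, exact sign-flip permutation p = 0.0312, the smallest possible). Only 3.19% ± 3.40 of isoCirc junctions were also called by CIRI-long (SD, n = 8), from 10.4% in the Nanopore pilot to 0 of 34 in the liver metastasis, while 31.8% ± 8.4 of isoCirc host genes had a CIRI-long junction in the same library. Without the pilot the junction share was 2.15%.

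HCT116 was sequenced 3 times, which allowed platforms to be set side by side. The Nanopore and PacBio libraries shared many of their leading circles, among those of named genes ASH1L exon 6 (1545 and 3944 reads), PTGR2 (405 and 1190 reads), PTPN18 (330 and 359 reads), TNS4 (228 and 727 reads), RREB1 (223 and 572 reads), AFF1 (208 and 859 reads) and RERE (167 and 382 reads). Of leading junctions with no gene symbol, a junction with 757 PacBio reads had 0 in Nanopore and another with 229 Nanopore reads had 14 in PacBio. The Nanopore pilot had 1 read of ASH1L and 0 of the 6 other named circles. It was led by circles of ERF (201 reads), GLB1 (177 reads) and ZDHHC20 (135 reads) with 0 reads in the other 2 libraries. Other leading junctions were read in all 3, a PTMS junction (31 pilot, 11 Nanopore and 22 PacBio reads) and one listed under SLC30A7 (20, 115 and 9 reads). The latter lies in a non-coding exon (chromosome 1, 633637 to 633944), and its gene name is only the deposited one. These junctions were chosen after their values were seen. Of Nanopore junctions with at least 2 reads, 82.4% (78.0 to 86.2) were found in PacBio, against 28.1% (19.4 to 38.2) of pilot junctions. After each library was thinned to 1391 reads the shares were 64.7% ± 3.7 and 12.3% ± 1.9 (SD over 100 draws). By CIRI-long 28.8% of Nanopore junctions were found in PacBio. These are values of single libraries with no test.

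**Figure D4:**
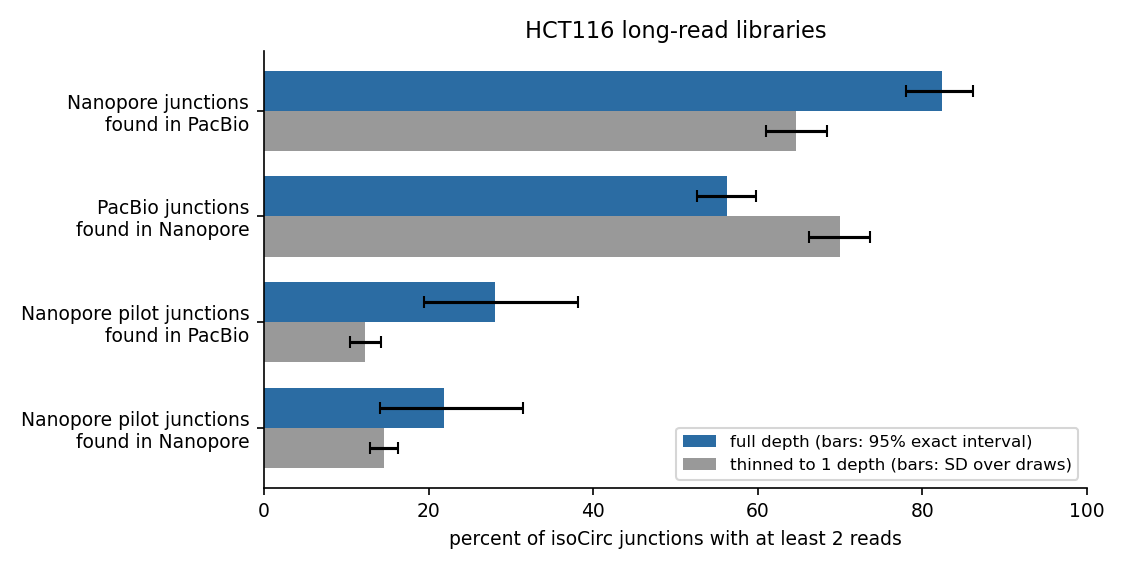
Percent (x axis) of isoCirc junctions of one HCT116 library found in another (y axis), at full depth with exact 95% intervals and after thinning to 1391 reads with SD over 100 draws. The Nanopore to PacBio share (82.4%) lies above both shares of the pilot (28.1% and 21.9%) at full depth and after thinning.

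The tissue libraries addressed how circles differ among normal mucosa, primary tumour and liver metastasis of 1 donor. The library labelled normal mucosa held junction reads of liver genes. By CIRI-long, 13 of 22 hepatocyte genes had 894 of its 28421 reads (3.15%, 2.95 to 3.36), against 0 of 20748 reads in the primary tumour (3 reads would be 0.0145%) and 0 of 9750 in the liver metastasis (3 reads would be 0.0308%). They included the complement gene C3 (248 reads), the protease inhibitor gene SERPINA1 (211 reads), the urea cycle gene CPS1 (164 reads), the serum albumin gene ALB (90 reads), AHSG (47 reads), ABCC2 (35 reads, all of a junction spanning 1 base), CP (34 reads), the fibrinogen gene FGB (32 reads), ITIH1 (11 reads) and the transferrin gene TF (9 reads). Of the SERPINA1 reads 133 lay in 1 short junction (chromosome 14, 94380895 to 94380932). Of the CPS1 reads 149 lay in a short intronic junction (chromosome 2, 210575505 to 210575552), and the leading ALB junction (28 reads) was also intronic. Only 0.776% of CIRI-long junctions of this library had both ends at annotated exon boundaries. isoCirc found 27 reads of 6 genes of the list in this library, led by C3 (9 reads), AHSG (8 reads) and SERPINA1 (7 reads). It found 0 reads of CPS1, ALB, ABCC2, CP and TF. Its 0 reads in the primary tumour and metastasis stand on small libraries, where 3 reads would be 0.226% and 0.397%. By CIRI-long the list's median log2 ratio of this library over the primary tumour (3.05) lay at percentile 99.9 of 10000 random lists matched on expression. By isoCirc, with 3 members and the floor of 3 reads, the median was −0.823, at percentile 83.6. These members (C3, AHSG and SERPINA1) had 0 reads in the primary tumour. The negative sign follows from the floor and the deeper library and gives no direction. Over the metastasis the percentiles were 98.1 by CIRI-long and 65.7 by isoCirc.

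By share of reads, colon epithelial genes went the other way across the labels. Differentiated colonocyte and goblet genes took 0.0176% (0.00571 to 0.0411) of CIRI-long reads in the library labelled normal mucosa, 0.164% (0.114 to 0.229) in the primary tumour and 0.656% (0.506 to 0.837) in the liver metastasis, and 0.0140% ± 0.0048 in the 3 PacBio lines (SD, n = 3). PIGR, which carries antibodies across the epithelium, gave 0, 27 and 48 reads and CEACAM1 0, 0 and 9. The colonocyte and goblet shares rest on 5, 34 and 64 reads. Epithelial genes took 0.0317%, 0.140% and 0.369%. Against matched random lists, the colonocyte and goblet median lay at percentile 15.5 for the library labelled normal mucosa over the primary tumour. It lay at 12.1 for that library over the metastasis and at 17.5 for primary tumour over metastasis. For epithelial genes the percentiles in this order were 48.4, 0.34 and 29.0. Fibroblast and matrix genes took 0.764%, 0.482% and 0.0410%, nearly all from the fibronectin gene FN1 (215, 96 and 4 reads), and smooth muscle genes 0.215%, 0.169% and 0.0410%, with DMD (49, 0 and 0 reads). Endothelial, immune, and enteric neural and glial genes each had at most 10 reads per tissue, and cell cycle genes had 0.

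**Figure D5:**
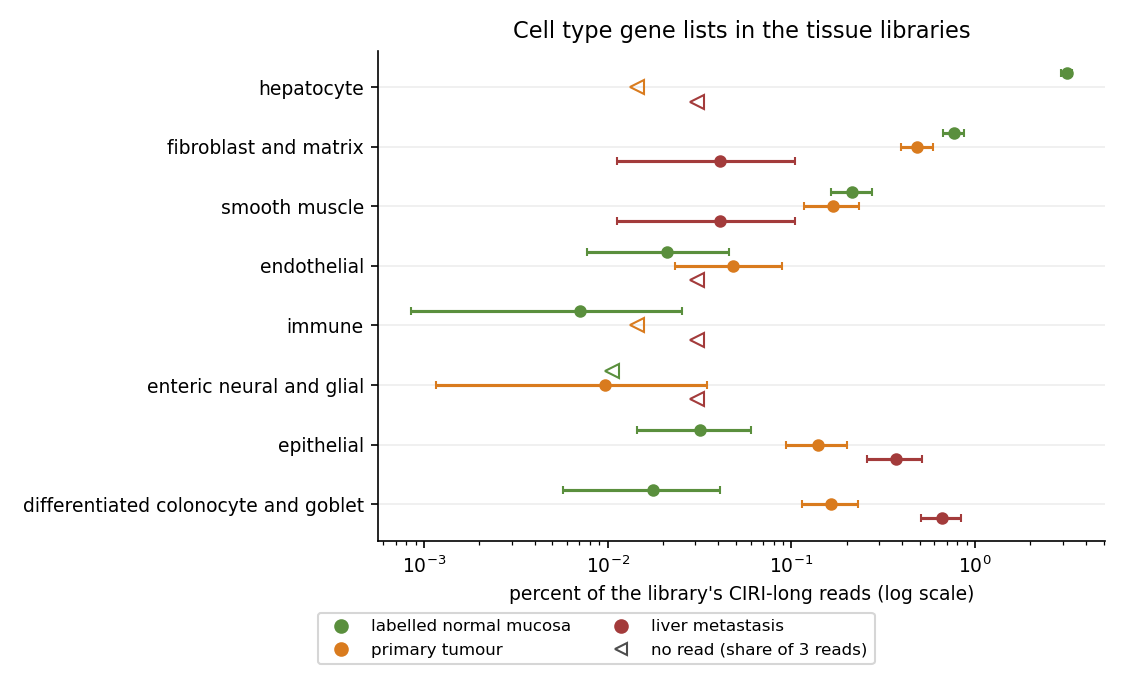
Percent of CIRI-long reads (x axis, log scale) in 8 cell type gene lists (y axis) for the 3 tissue libraries, with exact 95% intervals; open triangles mark lists with no read, drawn at the share of 3 reads. Hepatocyte genes reach 3.15% in the library labelled normal mucosa alone, and colonocyte genes are highest in the liver metastasis at 0.656%.

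By isoCirc each tissue was led by its own circles. The rule required the same direction in CIRI-long and left exons 7 to 10 of NSMCE4A, of a DNA repair complex (219 reads in the library labelled normal mucosa, at least 15.5-fold above the primary tumour and 8.78-fold above the metastasis, each at 0; chromosome 10, 121959324 to 121961517), and ARHGAP1 (26 against 0 reads in the primary tumour, at least 1.84-fold). The following were chosen after their values were seen and had no CIRI-long read in the tissues compared. USP43 had 2541 reads in the library labelled normal mucosa, 40.5% of its isoCirc total, while UTRN had 434, GPT2 261 and MLIP 78. The primary tumour held LINC01828 (48 reads), SUSD6 (39 reads), PTPRA exons 8 to 9 (37 reads), RAPGEF5 (24 reads), CCAR1 (23 reads) and TOM1 (20 reads), each at 0 in the other tissues. The liver metastasis held an intron of PLS1, from an actin bundling gene of the brush border (330 reads, 43.7% of its total; chromosome 3, 142606204 to 142606533), MGRN1 (117 reads, and 2 in the primary tumour), PARD3B (110 reads), GALNT10 (25 reads), and THSD4 and ARID1A (7 reads each).

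Junctions with at least 10 reads and a 4-fold difference numbered 35 between the library labelled normal mucosa and the primary tumour (10 higher in the first and 25 in the second), 13 between primary tumour and metastasis (8 and 5), and 10 between the library labelled normal mucosa and metastasis (5 and 5). With TMM factors the pairs with the library labelled normal mucosa gave 57 (32 and 25, so more were then higher in the first) and 27 (22 and 5). On library totals a minimum of 5 reads gave 10 and 47, 8 and 10, and 5 and 11 for the 3 pairs in the same order, and of 20 reads 10 and 9, 8 and 4, and 5 and 4. With the floor of 3 reads, a junction needed more reads to reach 4-fold in the deeper library of a pair. Totals were 6274 isoCirc reads in the library labelled normal mucosa, 1330 in the primary tumour and 755 in the metastasis. The splits by direction thus depend on depth and do not compare the tissues alone. By CIRI-long counts the 3 pairs gave 582, 224 and 231. Few junctions were read in both members of a pair (21, 3 and 2 by isoCirc), and with 1 library per tissue there is no replicate check.

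The 3 PacBio lines were compared with the 3 tissues for circles of cultured cancer cells against tissue. Summed over junctions, PTMS had 345, 16 and 115 isoCirc reads in HCT116, HT29 and LoVo and 3, 0 and 0 in the tissues. GPT2 had 23, 2 and 46 against 350, 32 and 0. By CIRI-long, the nuclear lamina gene LMNA (183, 118 and 69 reads) and the chromatin gene HMGA1 (237, 45 and 11 reads) were read in the 3 lines with 0 reads in the tissues, and FN1 in the 3 tissues with 0 in the lines. FKBP8 gave 4, 12 and 10 reads in the lines and 27, 6 and 1329 in the tissues, so its value rests on the metastasis library. None of these passed the test. The filter on low counts left 1 isoCirc junction, NPTN (chromosome 15, 73561896 to 73563257; 0, 30 and 16 reads in the lines and 51, 0 and 0 in the tissues), and edgeR's quasi-likelihood test called 0 junctions (adjusted p = 0.767; 0 at unadjusted p under 0.05). CIRI-long host gene sums gave 0 calls among 65 genes and 6 at unadjusted p under 0.05, with FKBP8 at an adjusted p of 0.0903, FN1 at 0.108, LMNA at 0.138 and HMGA1 at 0.146 (edgeR). DESeq2 without the filter called 0 of 4640 isoCirc junctions (4 at unadjusted p under 0.05), and on CIRI-long it called 4 junctions read in LoVo alone and 1 host gene, CHST1, read in the primary tumour alone (73 reads). Without the HCT116 library edgeR called 1 junction, TMBIM1, and without HT29 2 junctions, both PTMS. The test was also run without the filter on simulated host gene counts. At a dispersion of 0.1 it recovered 33.3% of 16-fold changes for isoCirc and 49.5% for CIRI-long. Of 4-fold changes it recovered 2.47% and 12.9%. At the dispersions of the unfiltered host gene fits (6.03 and 6.10) it recovered 0% of either fold. The filtered fit of 65 CIRI-long host genes had a dispersion of 2.42, which was not simulated.

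Hepatocyte genes were the gene list that stood lowest in the lines, and every read behind this in the tissues came from the library labelled normal mucosa. With the filter on low counts 0 of 13 lists had the 3 members needed for limma's camera test. Without the filter, camera with a preset correlation called the hepatocyte list lower in lines on isoCirc sums (6 members, adjusted p = 9.78e-05; adjusted p = 0.434 with an estimated correlation). On CIRI-long sums it called hepatocyte (13 members, adjusted p = 9.2e-06), fibroblast and matrix (4 members, adjusted p = 0.00743) and differentiated colonocyte and goblet genes (8 members, adjusted p = 0.0412), all lower in lines; with an estimated correlation the adjusted p were 0.441, 0.360 and 0.360. Not called were the smooth muscle, endothelial, epithelial, Wnt and colorectal driver, cell cycle, splicing and circle formation, and well-described circle host lists. No member passed edgeR's test over all genes or adjusted over the list alone, and without the library labelled normal mucosa 0 of 4 lists were called on isoCirc sums and 2 of 8 on CIRI-long sums.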

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

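The tests of a shared amplification product, of depth and of the cell line alone, of the caller overlap, and of liver RNA, mucosa RNA and a swap were chosen only after the results they bear on had been seen; the share of the leading hepatocyte junctions was set beforehand. Of 55 sets of libraries examined, 19 held a library far from the others, and 14 of these are junctions picked because a single line held them, which makes them stand apart by construction. Chance alone gives about 1 in 20.

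Hepatocyte genes had 894 CIRI-long reads in the library labelled normal mucosa and 0 in the other tissues. Colon mucosa RNA alone is argued against by ALB, AHSG, FGB, ITIH1 and TF, which together gave 189 reads in 30 junctions there and 0 reads in each of the 7 other long-read libraries. A few heavily amplified junctions may set much of the amount, since 3 of 71 junctions held 52.9% of the list's reads, although 13 genes were represented. Liver RNA in that library, from a mixed sample or a wrong label, is consistent with the 3.15% share, which lies above the intervals of the primary tumour and metastasis. A swap with the metastasis library cannot be told apart: that library held the highest share of colonocyte and goblet genes (0.656%), which a metastasis of a colon tumour can also hold and which rests on few junctions (82.8% of reads in 3 of 8, and 48 of 64 reads from PIGR).

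The HCT116 Nanopore and PacBio libraries shared circles that the pilot lacked. Sequencing depth is argued against by 64.7% of thinned Nanopore junctions being found in thinned PacBio, against 12.3% for the pilot. The cell line alone is argued against by 28.1% of pilot junctions being found in PacBio at full depth, below the interval of the Nanopore share. A shared amplification product cannot be told apart: reads of 548 shared junctions had rho 0.679 in Nanopore and PacBio and 0.201 and 0.252 in the HCT116 pairs with the pilot, but LoVo and the library labelled normal mucosa, of different origin, reached 0.696 over 25 junctions. The platforms themselves were not separated from the preparation, and the design gives no biological difference to test.

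The callers shared few junctions. Small coordinate differences are argued against as the whole cause, since a tolerance of 10 bases gave 5.31%. Low read counts are likewise argued against as the whole cause (8.41% at 20 reads). Ends outside annotated exon boundaries cannot be judged. Of isoCirc junctions with both ends at boundaries 4.15% were shared, but only 1.62% ± 1.09 of CIRI-long junctions had such ends (SD, n = 8). Few exact matches were therefore possible. No biological explanation was tested. What the algorithms do with repeated copies in a read stays open.

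Other libraries that stood apart are given as values. The median number of exons per circle was 3 in HCT116 and 4 in the other short-read lines. With the other medians equal, any different value would have stood apart, so this case carries little information. HT29 had 0.535% of short reads in cell cycle genes, with 0.266% to 0.339% in the others, led by ATAD2 (36 reads). SW620 had 4814 CPM of ZKSCAN1 exons 3 to 5, with 1820 to 2613 CPM elsewhere. The Nanopore pilot had 10.4% of its isoCirc junctions in CIRI-long, with 0% to 4.76% in the 7 other libraries.

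Junctions found mostly in single short-read lines were, in CPM, CYP24A1 (10250), USP34 (1031) and PTOV1 (364) in HCT116, ADAMTS6 (4282), PTK2 (2355) and GNAQ (321) in HT29, and SEMA3C (2736), CTBP2 (418) and COCH (836) in LoVo. In SW480 they were CERS6 (1236), SFMBT1 (449.6) and AHNAK (365), and in SW620 PROX1 (2063), GLI3 (952) and SDK1 (794).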

How the results depend on the processing

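The tolerance of 10 bases, the minimum of 20 reads, the subsets by exon boundary and span, the average over HCT116 libraries, CIRI-long host gene sums, DESeq2 without the filter, list tests in combined settings and the counts of splits were chosen only after results had been seen. Directions of the caller difference held at every read minimum and with HCT116 averaged (mean log2 ratio −3.16). For lines against tissues, no paired analysis was possible because no line comes from the donor of the tissues. The cause of a change was not tested except where a setting by itself changes what is counted.

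For junctions differing between lines and tissues (0), leaving out each library gave 0 to 2, and DESeq2 without the filter gave 4 on CIRI-long junctions and 1 on CIRI-long host genes; every other setting gave 0. CIRI-long host gene sums gave 0 to 1 when each library was left out (1 without the metastasis, UBE2S). Gene lists (0 tested with the filter) gave 1 without the filter, 3 without the filter on CIRI-long counts and 2 without the filter on library totals (hepatocyte, and splicing and circle formation genes, adjusted p = 0.0442, or 0.390 with an estimated correlation), and on isoCirc sums 0 to 2 when each library was left out (0 without the library labelled normal mucosa). On CIRI-long sums leaving out each library gave 1 to 3 (2 without the library labelled normal mucosa). The caller share moved from 3.19% to 1.63% at 1 read, 5.49% at 5 reads, 8.41% at 20 reads and 5.31% within 10 bases. Short-read recovery moved from 3.97% to 1.84% at 1 short read, 10.0% at 5, 22.4% at 20, 0.141% with CIRI-long and 5.75% for spans under 1000 bases, and stayed within 3.39% to 4.94% without each line. Long-read junctions not found by short reads moved from 81.2% to 73.6% against any short-read library, 99.8% with CIRI-long, 65.1% with both ends at exon boundaries and 100% with at most 1, and stayed within 79.3% to 84.3% without each line. Of all short-read junctions 99.2% had both ends at exon boundaries, so the 100% was nearly fixed beforehand. Nanopore junctions found in PacBio moved from 82.4% to 28.8% with CIRI-long and 64.7% after thinning.

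Counts of 4-fold differences followed the setting. Between the library labelled normal mucosa and the primary tumour 35 became 57 with TMM, 582 with CIRI-long, 57 at 5 reads and 19 at 20 reads. Between the primary tumour and metastasis 13 became 224 with CIRI-long. Between the library labelled normal mucosa and metastasis 10 became 27 with TMM, 231 with CIRI-long and 16 at 5 reads. Between SW480 and SW620 67 became 109 with TMM, 103 at 5 reads, 40 at 20 reads and 254 on the deposited scale. Junctions per short-read line moved from 3722 to 10562 at 1 read and 835 at 5 reads, and stayed within 3291 to 3957 without each line. Strand-matched overlap, DESeq2 size factors and DESeq2 on the filtered junction were not run.

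None of the 10 ways to split the 6 PacBio libraries can give a share under 0.05. The real split gave 0 junction calls, the highest other 1, and 10 splits gave as many. CIRI-long host genes at unadjusted p under 0.05 numbered 6, the highest other 5, and 1 split gave as many. Lists without the filter numbered 1 on isoCirc sums (highest other 2, 6 splits as many) and 3 on CIRI-long sums (highest other 3, 2 splits as many).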

Other observations

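All values in this part were computed only after the junction tables had been examined, and none tests an explanation. In the short-read lines circles most often began at exon 2 of the host transcript, 33.3% ± 2.2 of junctions (SD, n = 5) and 40.7% ± 2.9 of reads, followed by exon 3 with 14.0% ± 0.5. Exon 1, which lacks an upstream splice acceptor, began 0.188% ± 0.092. Circles of 2 to 5 exons made up 70.4% ± 1.3 of junctions and single exons 6.18% ± 0.83.

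Circles of the short-read lines came from 4520 host genes, of which 1859 had 1 junction and 221 had 10 or more. BIRC6, a large inhibitor of apoptosis gene, had 44 junctions and no dominant circle, its leading junction holding 15.5% of 232 reads. PTK2 had 41 junctions, the chromatin gene SMARCC1 36, UBAP2 35 and LRBA 32. In DNA2 the leading junction held 48.1% of 268 reads, and in the nuclear export gene XPO1 42.1% of 354 reads. Among isoCirc junctions, 2.11% (liver metastasis) to 11.8% (HCT116 Nanopore) had several internal structures for the same ends.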
